A study of Rattus norvegicus with 56 samples.

How the data were processed

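The data are ChIP-seq peak lists from brain tissue of rats with intracerebral haemorrhage, for H3K4me3, H3K9ac and H3K27me3 on the ipsilateral and contralateral side at 13 and 21 months, and for H3K9ac and H3K27me3 in ipsilateral tissue of 21-month rats given plasma of 3-month or 22-month rats. Sheared chromatin was immunoprecipitated and libraries were made with a ThruPLEX DNA-seq kit and sequenced on a NextSeq instrument, per the labels' protocols. There are 28 ChIP and 28 input libraries in 16 lists. Each of the 12 lists without plasma pools 2 ChIP and 2 input libraries, and each of the 4 plasma lists uses 1 of each, per the file headers. Groups were taken from the labels. The labels do not say whether the libraries of a group come from separate animals.

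The submitters' processing notes name cutadapt, Bowtie2 and HOMER, without versions or roles. Peaks were called with MACS 2.1.1.20160309 in narrow mode at a q-value cutoff of 0.05, with an effective genome size of 2.70 Gb, single-end handling of tags and at most 1 tag kept per position, per the file headers. The genome build is not given in the sources used here. Coordinates are printed as the lists give them, 1-based, on the build the authors used. For each peak the authors' lists hold the pileup, a signal (coverage) value scaled to the smaller of the ChIP and input totals of that list, the fold enrichment, a ratio to the local background, and the −log10 p-value, which was not used, and −log10 q-value, per the file headers. The signal is scaled differently in each list and was not compared across lists. Fold and −log10 q-value as deposited by the authors were used to describe, rank or filter peaks, and the folds of a region and the counts of peaks past a fold of 8 were also set side by side between lists, where no correction for the depth or background of each list was made. Strong duplication lowers the tags kept: duplicates made up 13% to 82% of ChIP tags and 9% to 45% of input tags. Tags kept per list were 19323327 to 117740131 for ChIP. H3K27me3 forms broad domains, which narrow calling can break into many short peaks. The file paths in the headers place the lists in 7 folders, called processing runs here. Each mark and age without plasma has its own, with both sides together, and all plasma lists share 1 further folder. The paths do not say which libraries were prepared or sequenced together.

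From the lists, peak numbers, covered bases and lengths were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. In place of bedtools, overlap was computed on sorted intervals in Python. Lists of a mark were compared in 18 pairs: side at each age, age on each side, plasma of 3-month against 22-month rats, and each plasma against none. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp, and shares were set beside the mean of 100 seeded random placements of the peaks on their own chromosomes, which ignore gaps and unmappable sequence. Chromosome lengths for the placement were the highest peak ends over all lists. Overlapping peaks of the 4 untreated lists of a mark were joined to regions. Regions that differed in both comparisons of a kind were put in a 2 by 2 table of directions with an odds ratio, a 95% Wald interval and Fisher's exact test, two-sided, over regions and not animals, with Benjamini-Hochberg adjustment over the 6 tables. Constitutive H3K4me3 regions are those with a peak in all 4 H3K4me3 lists (18912 regions, median length 1626 bp). Shares of them have 95% Wilson intervals.

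The design fixed before the data were examined was written for promoters and gene lists. No annotation of the coordinates' build was used here, so genes were not assigned, and regions took the place of promoters and genes. The rule for named items was kept with regions in place of genes and the authors' fold in place of the tag value. For each mark these were the 5 regions with a peak on 1 side at both ages, or at 1 age on both sides, and in neither other list. They were ranked by the lower of the 2 folds. For plasma they were the 5 regions of highest fold with a peak in 1 plasma list and not the other, whether or not untreated tissue had a peak. Tag ratios between lists, gene lists, cell type markers and tests over replicates were left out, since the lists give no values that are comparable across lists and none per library. H3K4me3 regions with H3K9ac or H3K27me3, the domains of H3K27me3 and the relation of H3K9ac to H3K27me3 were added after the data were seen. The direction table for the sides was tested on simulated data, and that for age was not. There were 50 sets of 4 lists of the real lengths over 56333 H3K4me3, 199844 H3K9ac and 493767 H3K27me3 regions. With 200 regions raised on the ipsilateral side, 113, 103 and 76.4 of them on average fell in the ipsilateral-only group and 0 in the opposite group. With no change the test passed 0.05 in 10.0%, 0% and 10.0% of sets, but in 100.0% of sets for each mark when lists differed in noise, so an odds ratio away from 1 does not by itself show regional change. Alternatives were a fold of at least 8, equal numbers of the strongest peaks by q-value (30356 for H3K4me3, 50651 for H3K9ac and 37241 for H3K27me3), an overlap of at least 50% of the smaller peak, peaks within 1 kb joined, bases in place of peaks, regions of at least 1 kb, and regions widened by 1 kb.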

Results

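Histone modifications were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the brains of rats with intracerebral haemorrhage, a bleed into the brain tissue. The marks were H3K4me3, which lies at active and poised promoters, H3K9ac, which lies at active promoters and enhancers, and H3K27me3, the repressive mark laid down by Polycomb complexes. Tissue from the ipsilateral side (the side of the haemorrhage) and from the contralateral side was taken from rats whose sample labels give 13 or 21 months of age; the series text gives 22 months for the older rats. For H3K9ac and H3K27me3, ipsilateral tissue of 21-month rats given plasma of 3-month or of 22-month rats was profiled as well. Each age, side and mark had 2 ChIP and 2 input libraries, and each plasma group had 1 of each, 56 libraries in all. The authors' 16 peak lists give 1 list per group, with the libraries of a group pooled before peak calling, so there is no spread between replicates behind any value and no test of the groups. Where a binomial interval over regions is given, it covers counting error only.

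The peak caller kept between 19323327 ChIP tags, for H3K9ac in 13-month ipsilateral tissue, and 117740131, for H3K27me3 in 21-month ipsilateral tissue. The 4 H3K4me3 lists were alike in size, with 30356 to 35063 peaks that covered 27.1 to 37.5 Mb. H3K9ac lists held 50651 to 123863 peaks. H3K27me3 lists ranged most widely, from 37241 peaks over 17.6 Mb with plasma of 3-month rats to 367061 peaks over 197 Mb in 21-month contralateral tissue. In the 13-month ipsilateral H3K9ac libraries 82% of tags were duplicates, against 55% on the contralateral side and 13% to 22% at 21 months without plasma.

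**Figure D1:**
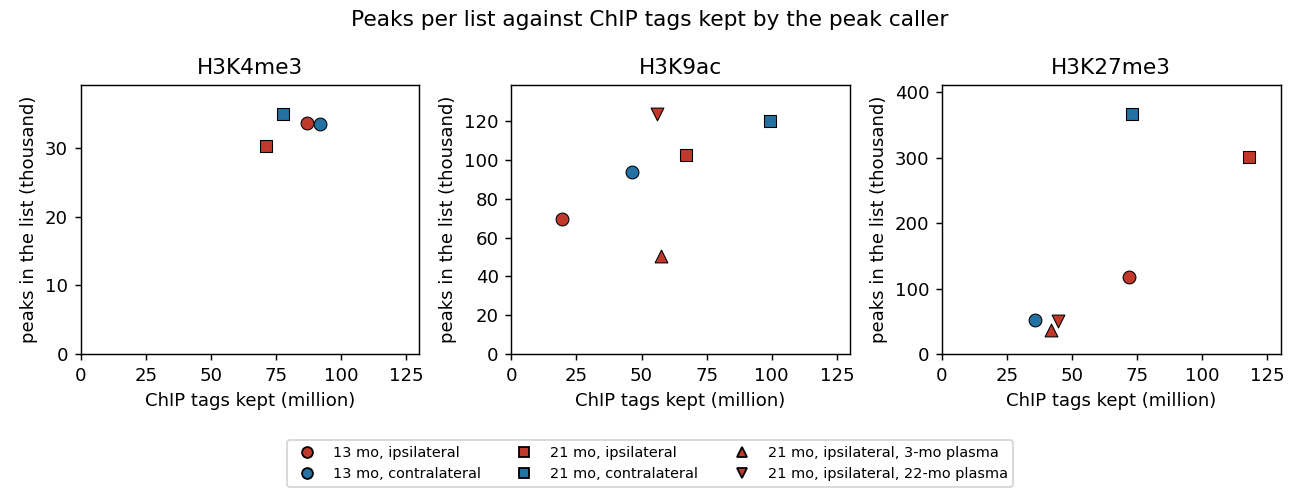
Number of peaks in each list (vertical axis) against the number of ChIP tags the peak caller kept (horizontal axis), 1 panel per mark, with colour for the side and marker shape for the age and plasma group. The 21-month contralateral and 13-month ipsilateral H3K27me3 lists stand at 73142126 and 71635071 tags with 367061 and 117866 peaks.

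The first comparison asked where the haemorrhage side differs from the other side in promoter-type chromatin. Strong H3K4me3 peaks were shared by both sides at both ages. At 13 months 65.0% of ipsilateral peaks overlapped a contralateral peak and 68.7% the other way, and at 21 months the shares were 81.6% and 65.3%. Randomly placed peaks of the same widths gave 1.99% to 2.66%. Of 10319 ipsilateral peaks at 13 months with a fold over input (the authors' own value for each peak) of 8 or more, 5 had no contralateral peak, and 2 of 10050 lacked a partner the other way. At 21 months these numbers were 1 of 12420 and 23 of 15064. Peaks found on 1 side alone were weak: the median fold of 13-month ipsilateral peaks was 3.02 where unshared and 7.64 where shared.

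When the 4 H3K4me3 lists were joined, 56333 regions resulted, of which 18912 held a peak in all 4 lists. Peaks on the ipsilateral side at both ages and in neither contralateral list were found in 540 regions, and the reverse in 662. These counts depended on the peaks entered. They were 580 and 457 with equal numbers of peaks per list and 25 and 170 with a fold of 8 or more. In the latter setting a weaker peak counted as absent. Regions with such a fold on 1 side at both ages and no peak of any fold on the other numbered 0 for either side. Of the 5 strongest ipsilateral-only regions over all peaks, 3 lay on chromosome 4. The region at chromosome 4, 163112083 to 163112544 had folds of 6.55 at 13 months and 5.96 at 21 months. On the same chromosome, the regions at 163224736 to 163225786 and 163226053 to 163226807 had folds of 5.26 and 5.96 at 13 months and 5.32 and 5.16 at 21 months. The other 2 of the leading 5 lay at chromosome 3, 121880246 to 121882686, with folds of 5.62 and 5.70, and at chromosome 1, 73009546 to 73010886, with 5.33 and 6.01. The leading 5 contralateral regions were short, 157 to 202 bp. They were led by chromosome 2, 155281994 to 155282180, with folds of 6.42 and 11.3.

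Of the H3K4me3 regions that differed between the sides at both ages, 540 were ipsilateral at both and 662 contralateral at both, while 875 were ipsilateral at 13 and contralateral at 21 months and 138 the reverse. The odds ratio for the same direction was 2.96 (95% interval 2.39 to 3.66) by Fisher's exact test, two-sided, which counts regions and not animals. With a fold of 8 or more it was 1.62 (95% interval 0.760 to 3.46), no longer past the threshold. The largest of the 6 exact p-values of this kind, over the 3 marks and the comparisons of side and of age, was 2.99e-19, and it was the same after Benjamini-Hochberg adjustment. Neighbouring regions are not independent, so these p-values are too small. In simulated lists of the same lengths with no regional change the odds ratio for the side had a median of 1.00 and ran from 0.855 to 1.11. Its median was 1.71 when both contralateral lists were given less noise.

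Between 21 and 13 months, 73.6% of the 21-month ipsilateral H3K4me3 peaks and 59.1% of the contralateral ones overlapped a 13-month peak of the same side. The widest H3K4me3 domain at 13 months on the contralateral side, chromosome 2, 11865664 to 11886835, spanned 21172 bp, and it was the widest in each of the 4 lists, reaching 27935 bp in 21-month contralateral tissue. Peaks of 5 kb or longer numbered 25 on the contralateral and 42 on the ipsilateral side at 13 months, and 230 and 92 at 21 months. Peaks at 21 months on both sides and at neither side at 13 months were found in 1590 regions, and the reverse in 214. These counts were 1596 and 153 with equal numbers of peaks per list and 1371 and 5 with a fold of 8 or more. In the latter setting a weaker peak counted as absent. Regions with such a fold on both sides at 21 months and no 13-month peak of any fold numbered 0, and the reverse 1. The direction of change was shared by the sides with an odds ratio of 2.82 (95% interval 2.24 to 3.54). With a fold of 8 or more it was 2.62 (95% interval 0.887 to 7.72) and not past the threshold. The strongest region of the 13-month group was at chromosome 20, 132349 to 132745, with a fold of 10.5 on the contralateral side and a higher one on the ipsilateral side, and the next, at chromosome 6, 140109100 to 140109327, had 7.82 on the ipsilateral and 6.16 on the contralateral side. In the 21-month group the region at chromosome 20, 189119 to 189337 had folds of 7.33 and 12.4, and that at chromosome 7, 10509150 to 10509356 had 7.14 and 8.15. The 13-month and 21-month lists of every mark lay in separate processing runs, so age and run cannot be told apart. Both sides of an age shared a run, though whether their libraries were prepared together is not known.

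**Figure D2:**
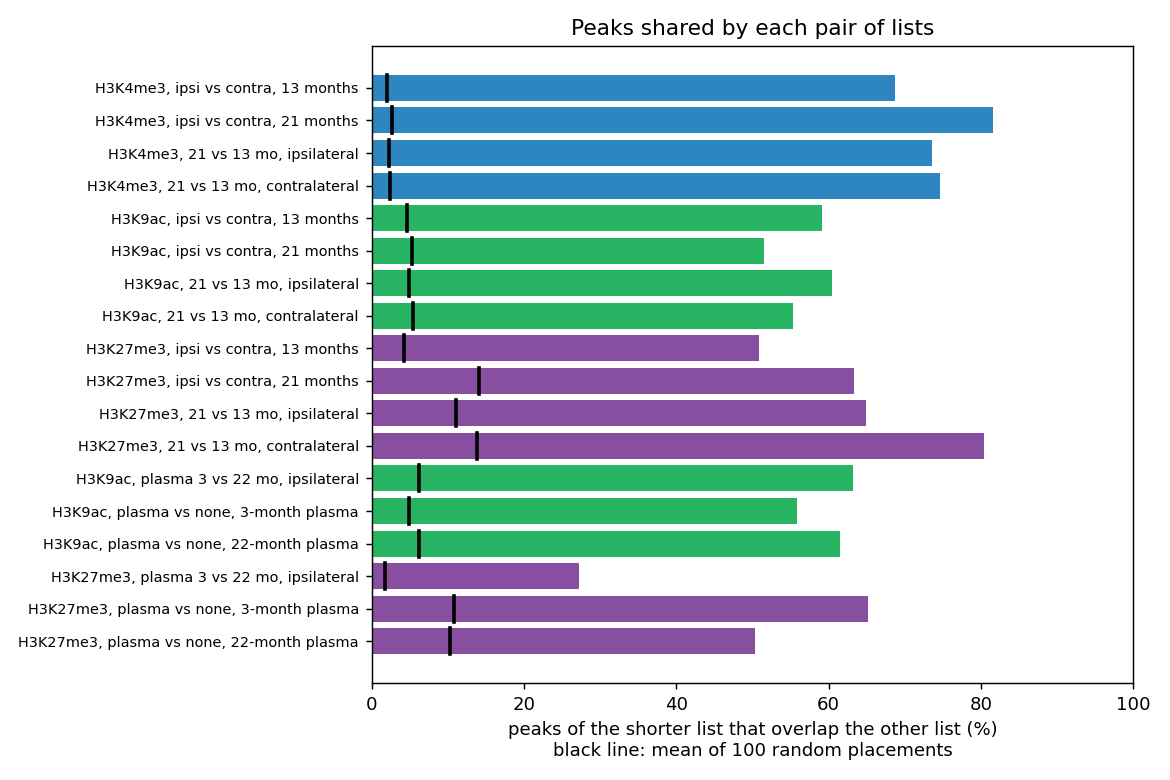
Percentage of the peaks of the shorter list of each pair that overlap the other list by 1 bp or more (bars, coloured by mark), with the mean of 100 random placements of the same peaks (black lines). H3K4me3 pairs shared 68.7% to 81.6%, and the lowest bar is the pair of H3K27me3 plasma lists, at 27.3%.

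H3K9ac marked most constitutive H3K4me3 regions, that is the 18912 regions with an H3K4me3 peak in all 4 lists. At 13 months 92.3% (91.9 to 92.6) of them had an H3K9ac peak on the ipsilateral (95% Wilson interval) and 95.3% on the contralateral side, and at 21 months 96.0% (95.7 to 96.2) and 93.8% (93.4 to 94.1). Over all peaks the side with more marked regions thus differed by age. At 13 months 867 regions had H3K9ac on the contralateral side alone and 295 on the ipsilateral side alone. At 21 months these counts were 401 and 816. With only peaks of fold 8 or more, the difference at 13 months turned round, from -3.02 to 1.55 percentage points (ipsilateral minus contralateral). That at 21 months was then 23.6, so the ipsilateral share was the higher one at both ages. With equal numbers of peaks the differences were -2.22 and 4.14. The ipsilateral lists kept 0.417 (13 months) and 0.674 (21 months) times the ChIP tags of the contralateral ones.

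Over all H3K9ac peaks, 59.1% of the ipsilateral peaks at 13 months and 51.6% at 21 months overlapped a contralateral peak, against 4.62% and 5.30% with random placement. Regions with a peak on the ipsilateral side at both ages alone numbered 3057, and on the contralateral side at both ages alone 7068. They numbered 2069 and 2357 with equal numbers of peaks per list and 319 and 48 with a fold of 8 or more. The order thus turned round in the last setting, where a weaker peak counted as absent. With such a fold at both ages and no peak of any fold on the other side, there was 1 ipsilateral region and 0 contralateral ones. At 21 months the lists held 5736 ipsilateral and 1215 contralateral peaks of fold 8 or more. On assembled chromosomes the strongest ipsilateral-only region over all peaks lay at chromosome 1, 251575461 to 251576812. Its folds were 7.05 at 13 and 5.75 at 21 months. Next came chromosome 1, 247999572 to 247999948, with 5.99 and 5.63, and chromosome 4, 155410813 to 155411695, with 5.68 and 5.47. The leading 2 lay on unplaced scaffolds, with folds of up to 30.9. The strongest contralateral ones included chromosome 8, 91644599 to 91645428, with folds of 6.02 and 6.56, and chromosome 8, 118087727 to 118089265, with 5.97 and 6.41.

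More regions changed side between the ages than kept it. Peaks that were ipsilateral at 13 and contralateral at 21 months numbered 4640 and the reverse 9083, and the odds ratio for the same direction was 0.513 (95% interval 0.485 to 0.542) by Fisher's exact test. For change with age, 6899 regions had a peak at 21 months alone on both sides and 1607 at 13 months alone on both sides. The same 9083 and 4640 regions changed in opposite directions on the sides, an odds ratio of 0.263 (95% interval 0.247 to 0.281). The odds ratios for side and age share these counts, so the second is not independent of the first. With equal numbers of peaks per list the counts at 21 months alone and at 13 months alone were 1710 and 1496. They were 27 and 3669 with a fold of 8 or more, where a weaker peak counted as absent. Regions with such a fold on both sides at 1 age and no peak of any fold at the other numbered 0 for either age. For peaks of fold 8 or more the odds ratio for age was 3.83, in the other direction. For the comparison of sides, simulated lists of these lengths with no regional change gave a median of 1.01. The median was 0.605 where the 13-month contralateral and 21-month ipsilateral lists were given less noise than the others. The comparison of ages was not simulated.

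Among H3K9ac regions with a peak at 21 months on both sides and none at 13 months, the strongest was at chromosome 1, 148179689 to 148180011, with folds of 7.12 on the ipsilateral and 6.14 on the contralateral side, followed by chromosome 2, 12459956 to 12460632, with 7.33 and 5.55. The strongest with peaks at 13 months alone was at chromosome 6, 60444654 to 60445034, with 5.01 and 5.14. Of the 10681 peaks of fold 8 or more in 13-month ipsilateral tissue, 15 had no peak in the 21-month list, and of the 10152 on the contralateral side 5 had none.

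H3K27me3 peaks joined within 1 kb and kept only if common to the untreated lists gave 590 domains in which each of the 4 untreated lists covered at least 5 kb, and 587 and 560 of them also held a peak in the lists with plasma of 3-month and 22-month rats. Ranked by the lowest of the 4 coverages, the first domain, at chromosome 10, 84102231 to 84239779, was covered over 125 and 104 kb on the ipsilateral and contralateral side at 13 months and over 128 and 122 kb at 21 months. The next was at chromosome 1, 264392603 to 264573778, with 126, 80.2, 157 and 147 kb in the same order. Chromosome 7, 144505863 to 144591821, and its neighbour at 144598144 to 144661298 were covered over 82.6 and 61.2 kb in 13-month ipsilateral tissue, and chromosome 3, 61628011 to 61693731, over 56.9 kb. The domain at chromosome 20, 6641708 to 6775042, was covered over 35.6 and 34.0 kb on the ipsilateral and contralateral side at 13 months. At 21 months it was covered over 95.2 and 110 kb in untreated tissue. With plasma of 3-month and 22-month rats it was covered over 5.98 and 0.721 kb, the lowest plasma coverage of the 15 first-ranked domains. The first domain, on chromosome 10, kept 105 and 105 kb with plasma, and the first on chromosome 7 kept 72.6 and 75.9 of 80.1 kb. Over the 590 domains the median covered length was 13.9 kb ipsilateral and 8.49 kb contralateral at 13 months. It was 21.2 and 19.6 kb at 21 months, and 6.54 and 5.79 kb with plasma of 3-month and 22-month rats. The domains were chosen by the untreated lists alone, so lower plasma coverage may follow from the choice. The plasma lists also covered only 17.6 and 21.6 Mb in all, against 161 Mb in untreated 21-month ipsilateral tissue. They came from 0.354 and 0.377 times the ChIP tags. Loss of domains with plasma was not tested.

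In number of peaks, H3K27me3 lists differed more with age than with side over all peaks, and more with side over peaks of fold 8 or more. Mean shares of the shorter list were 57.1% between the sides and 72.6% between the ages. Such a share depends on the length of the other list. With equal numbers of peaks the means were 44.1% and 51.1%. A second count of the equal-number lists, not tied to the shorter list, gave 37.6% and 47.8% between the sides at 13 and 21 months. It gave 45.3% and 47.6% between the ages on the ipsilateral and contralateral side. The order of side and age thus did not hold for every pair. The 21-month lists held 2.55 times as many peaks as the 13-month lists on the ipsilateral and 7.09 times as many on the contralateral side. With a fold of 8 or more these ratios were 1.99 and 1.68, while those of ipsilateral to contralateral peaks were 0.197 at 13 and 0.232 at 21 months. A 21-month counterpart was found for 64.9% of 13-month peaks on the ipsilateral and 80.4% on the contralateral side, or 48.7% and 53.6% with equal numbers of peaks. Of the 231847 ipsilateral peaks found at 21 months alone, 55.5% lay within 5 kb of a 13-month peak (23.4% with random placement), and of the 331513 contralateral ones 28.1% (12.9%). Their median fold was 2.56 and 2.93. In 108415 regions both sides had a peak at 21 months and neither had one at 13 months, and 643 regions showed the reverse, with an odds ratio of 7.83 (95% interval 7.12 to 8.62) for a shared direction. The counts were 3434 and 1094 with equal numbers of peaks per list and 102 and 9 with a fold of 8 or more. In the latter setting a weaker peak counted as absent. Regions with such a fold on both sides at 1 age and no peak of any fold at the other numbered 0 for either age. The age comparison crosses processing runs, and with equal numbers of peaks per list the odds ratio of 7.83 fell to 1.82.

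Between the sides, 50.8% of contralateral H3K27me3 peaks at 13 months and 51.2% at 21 months overlapped an ipsilateral peak, against 4.25% and 11.6% with random placement. All 334 ipsilateral peaks of fold 8 or more at 13 months, and all 663 at 21 months, had a contralateral peak. Contralateral lists held more such strong peaks, 1696 at 13 and 2853 at 21 months, of which 18 and 11 had no ipsilateral peak. Regions with a peak on the ipsilateral side alone at both ages numbered 11763, led by chromosome 5, 118312011 to 118312988, with folds of 6.08 and 5.46 at 13 and 21 months, and including chromosome 6, 77266751 to 77267924, with 4.96 and 5.44. Regions on the contralateral side alone numbered 2956, led by chromosome 1, 11971516 to 11971916, with folds of 10.6 and 13.2, and chromosome 10, 5463373 to 5463936, with 7.10 and 9.58. With equal numbers of peaks per list the counts of the ipsilateral and contralateral groups were 3096 and 2792. They were 3 and 712 with a fold of 8 or more, where a weaker peak counted as absent. The ipsilateral excess thus shrank with list length matched and turned round in the last setting. With such a fold at both ages and no peak of any fold on the other side, there were 0 ipsilateral regions and 1 contralateral one. The odds ratio for the same direction at both ages was 3.91 (95% interval 3.65 to 4.19) by Fisher's exact test. In simulated lists without regional change its median was 1.04, or 26.2 with less noise in the contralateral lists.

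Constitutive H3K4me3 regions carried H3K27me3 less often than H3K9ac. At 13 months 25.7% (25.0 to 26.3) had an H3K27me3 peak on the ipsilateral and 25.3% (24.7 to 26.0) on the contralateral side, and at 21 months 31.6% (30.9 to 32.3) and 38.9% (38.2 to 39.6). When every list was cut to its 37241 strongest peaks, the shares were 20.7% and 23.9% at 13 months and 20.2% and 23.1% at 21 months. The excess at 21 months was then gone on both sides, at -0.492 and -0.841 percentage points (21 minus 13 months), while the contralateral share was the higher one at both ages.

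Bivalent H3K4me3 peaks, those that overlap an H3K27me3 peak of the same age and side, were more frequent than random placement gave. At 13 months they numbered 6723 of 33661 H3K4me3 peaks on the ipsilateral side, against 5.27% at random, and 5941 on the contralateral side, 17.7% against 2.31%. At 21 months there were 8587, 28.3% against 14.1%, and 12865, 36.7% against 17.7%. With equal numbers of peaks the shares were 16.2% and 17.6% at 13 months and 16.6% and 20.9% at 21 months. The marks were mapped in separate libraries of brain tissue, so an overlap does not show both marks on the same chromatin. Random placement takes no account of where promoters lie.

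At the constitutive H3K4me3 regions, H3K9ac was less frequent where H3K27me3 was present in 3 of the 4 untreated groups and in both plasma groups. In 21-month contralateral tissue 88.3% of regions with H3K27me3 and 97.3% of those without it had H3K9ac, an odds ratio of 0.211 (95% interval 0.185 to 0.241). The odds ratio was 0.365 (95% interval 0.327 to 0.406) in 13-month ipsilateral and 0.664 (95% interval 0.575 to 0.766) in 13-month contralateral tissue. In 21-month ipsilateral tissue the shares were 95.9% and 96.0%, with an odds ratio of 0.978 (95% interval 0.837 to 1.14). With equal numbers of peaks that odds ratio was 0.859 (95% interval 0.753 to 0.980), which leaves out 1. With plasma of 3-month and 22-month rats it was 0.266 (95% interval 0.242 to 0.293) and 0.342 (95% interval 0.286 to 0.409). These intervals treat regions as independent and say nothing of the spread between animals.

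**Figure D3:**
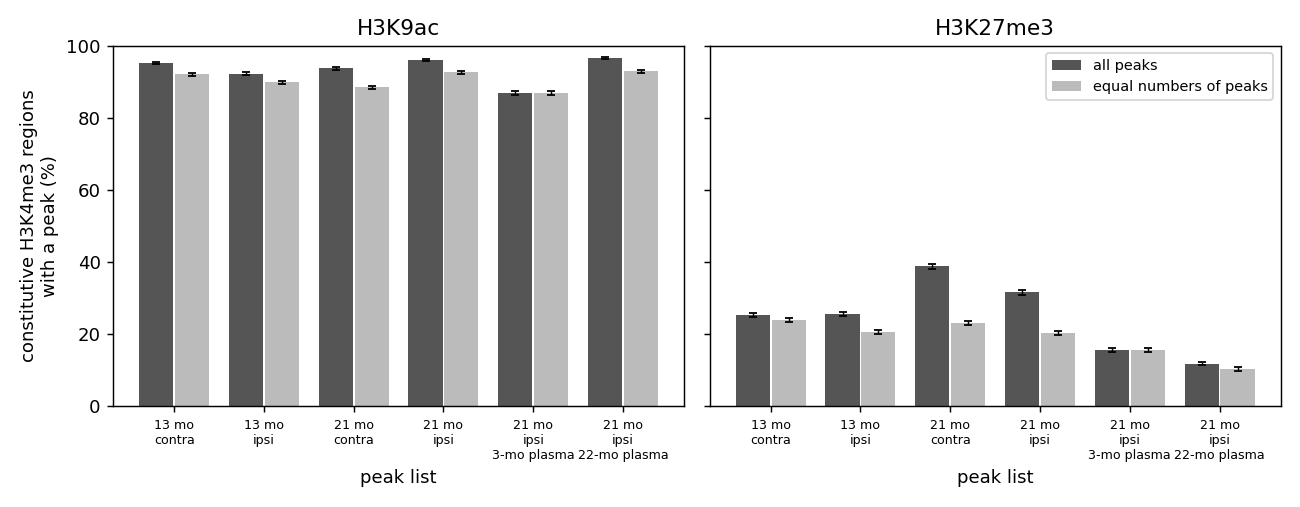
Percentage of the 18912 constitutive H3K4me3 regions with an H3K9ac peak (left) or an H3K27me3 peak (right) in each list, with all peaks (dark bars) and with equal numbers of peaks (light bars); error bars are 95% Wilson intervals over regions. With all peaks H3K27me3 runs from 11.8% with plasma of 22-month rats to 38.9% in 21-month contralateral tissue.

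The plasma groups asked whether plasma of young or old donors changes the chromatin of the ipsilateral side in 21-month rats. H3K9ac peaks were fewer with plasma of 3-month than with plasma of 22-month rats, at 50651 against 123863 peaks from 57426239 and 56130825 tags. Of the shorter list 63.2% was shared, against 6.28% at random. At constitutive H3K4me3 regions 87.0% (86.5 to 87.5) had H3K9ac with plasma of 3-month rats and 96.6% (96.3 to 96.8) with plasma of 22-month rats, and 1964 regions had it with the old plasma alone against 149 with the young plasma alone. With equal numbers of peaks these counts were 1531 and 403, and the difference (young minus old) went from -9.60 to -5.96 percentage points. Regions with the highest fold with young plasma alone were a pair on chromosome 1, 39255458 to 39256726 and 39271495 to 39272222, at folds of 8.50 and 8.45, neither with a peak in untreated tissue. With old plasma alone the highest was chromosome 20, 2706413 to 2707271, at 13.6, followed by chromosome 1, 266272869 to 266273950, at 10.8, where untreated tissue had 5.22. Each plasma list comes from 1 ChIP library, so a difference between them is one between 2 libraries.

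H3K27me3 peaks were less well shared by the plasma groups. The lists held 37241 peaks with young and 51178 with old plasma, and 27.3% of the first and 20.3% of the second overlapped, the first against 1.71% at random. At constitutive H3K4me3 regions 1036 had H3K27me3 with young plasma alone and 311 with old plasma alone, at shares of 15.7% (15.2 to 16.2) and 11.8% (11.4 to 12.3). The strongest region with young plasma alone was chromosome 20, 4647913 to 4648557, at a fold of 10.6 (6.35 in untreated tissue), and the longest of the leading 5 was chromosome 7, 57660579 to 57663660, at 7.90. With old plasma alone the strongest were chromosome 1, 265469252 to 265469685, at 16.3, and chromosome 3, 134026669 to 134027238, at 10.4, neither with a peak in untreated tissue.

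Against untreated ipsilateral tissue of 21-month rats, both H3K27me3 plasma lists were much shorter, from 0.354 (young) and 0.377 (old) times the ChIP tags. At constitutive H3K4me3 regions the difference in H3K27me3 from untreated tissue was -15.9 and -19.8 percentage points, but -4.55 and -9.89 with equal numbers of peaks. Of the peaks 65.2% with young and 50.3% with old plasma overlapped an untreated peak, against 10.9% and 10.3% at random. In the H3K9ac lists 55.9% and 46.4% did, against 4.85% and 5.03%. With equal numbers of peaks the shares were 39.1% and 26.6% for H3K27me3 and 47.8% and 64.4% for H3K9ac (the last of them a share of the untreated peaks), higher for H3K9ac with either plasma. H3K9ac was missing from both plasma lists and present in untreated tissue in 37114 regions. Independent lists would give 15255 and simulated lists with no change 12248. It was present in both and missing from untreated tissue in 4635, against 7874 and 5495. The independent values were taken over all regions. Only regions with an untreated peak can be lost, and only those without one can be gained, so these values are too low to measure an excess. For H3K27me3 the losses common to both were 265002, against 230771 and 231306, and the gains 1359, against 960.5 and 8. The simulation called 300668 of 335546 regions in the untreated H3K27me3 list, which leaves few to gain, so the 8 follows from that setting. The simulated noise was set and not fitted to the lists. A shared gain or loss therefore cannot be read from these values. Both comparisons use the same untreated list, so part of any excess may come from it. Plasma lists lay in a separate processing run from untreated tissue, with 1 library in place of 2.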

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

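The tests of depth, run, age and peak number below were chosen after the results were seen, as was the comparison with the plasma lists; the tests of H3K4me3-rich sequence, of the steepness of the fold and of carried material were chosen after the pattern was seen but fixed before their own values were, with that of carried H3K9ac material added last.

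The ratio of ipsilateral to contralateral peaks lay on opposite sides of 1 at the ages for 2 marks, though barely so for H3K4me3 at 13 months. For H3K27me3 it was 2.28 at 13 months and 0.819 at 21 months, and for H3K4me3 1.00 and 0.866. For H3K27me3 this held over all peaks only: with a fold of 8 or more both ratios lay below 1, at 0.197 and 0.232. With 1 pooled list per group these differences were not tested. The H3K27me3 ChIP tags kept had ratios of 2.01 and 1.61.

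H3K27me3 lists held more peaks at 21 than at 13 months. Depth does not account for all of it: the 21-month contralateral list had 3.11 times as many peaks as the 13-month ipsilateral list at 1.02 times the ChIP tags. Not every 21-month list held more peaks: the longer of the 21-month plasma lists held 0.988 times as many as the 13-month contralateral list. That pair also differs in side, run, treatment and number of libraries, so it cannot exclude an effect of age. What stays open is an effect of age and a difference between processing runs. None of the H3K27me3 runs (0) held both ages, so separate processing runs for the ages cannot be told apart from age.

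H3K9ac differences between regions ran opposite ways. The odds ratio for the same side at both ages was 0.513, and that for the same change with age on both sides 0.263, where values above 1 were found for the other 2 marks, and with a fold of 8 or more the latter turned round to 3.83 (2.45 to 5.98). Different numbers of peaks per list do not account for the first, which was 0.561 (95% interval 0.519 to 0.607) with equal numbers, nor does a tilt of some lists towards H3K4me3-rich parts of the genome, with 0.584 (0.539 to 0.634) within 10 strata of H3K4me3 regions within 500 kb. An exchange of the sides at 21 months may still explain the first. The 3-month plasma list, from ipsilateral tissue, shared 10.5 percentage points fewer peaks with the list labelled ipsilateral than with the one labelled contralateral (a difference of -10.5). The 22-month plasma list shared 5.51 points more, so the plasma lists do not decide. By itself an exchange would not account for the second. It would set the 6899 and 1607 regions that changed alike on both sides against 3057 and 7068, an odds ratio still below 1. Unequal noise between the lists also stays open, as does a real difference in how the sides change with age.

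Strong H3K27me3 peaks were shared by the contralateral lists: 712 regions had a fold of 8 or more on the contralateral side at both ages and on the ipsilateral side at neither, against 3 the other way. A steeper fold over input in the contralateral lists stays open: 99.9% of these regions held a weaker ipsilateral peak, but 99.4% of all strong contralateral peaks overlapped an ipsilateral one, so the measure is saturated, and a denser mark on the contralateral side would give the same value. Of these regions 76.1% lay on constitutive H3K4me3 regions, as H3K4me3 or H3K9ac material carried into the contralateral libraries would need. Such material would bring the strongest peaks of its mark first, but of the 1000 strongest 21-month contralateral peaks only 6.90% (H3K4me3) and 10.4% (H3K9ac) overlapped a contralateral H3K27me3 peak of 21 months, and 1.40% and 2.20% one of 13 months, which argues against it as the whole cause. A biological difference between the sides in how densely the regions are marked stays open and was not tested.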

How the results depend on the processing

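No paired analysis was possible because the libraries of a group were pooled before peak calling and the lists hold no value per replicate. For the same reason leaving out replicates, count models and tag ratios were not run, and the promoter windows and gene lists planned were not run because genes were not assigned. The alternatives for direction tables other than equal numbers, and those for H3K4me3 regions, bivalent peaks with widening, the relation of H3K9ac to H3K27me3 and ratios of peak numbers, were chosen after seeing the data. Over all results 61 alternative values stayed within the interval, threshold or range of 1.5 times used, 86 moved without changing direction, 15 changed direction, 2 no longer passed the threshold and 1 newly passed it. The causes were not tested, except that fewer peaks enter under a fold of 8 or more and under equal numbers.

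The share of the shorter list's peaks that overlapped the other list, averaged over the pairs of a kind, was, between the sides 75.2% (H3K4me3), 55.4% (H3K9ac), 57.1% (H3K27me3), between the ages 74.1% (H3K4me3), 57.9% (H3K9ac), 72.6% (H3K27me3), between the plasma donors 63.2% (H3K9ac), 27.3% (H3K27me3), between plasma and none 58.7% (H3K9ac), 57.8% (H3K27me3). With equal numbers of peaks, mean shares were, between the sides 76.8% (H3K4me3), 57.4% (H3K9ac) and 44.1% (H3K27me3), between the ages 75.7% (H3K4me3) and 51.1% (H3K27me3), between the plasma donors 52.2% (H3K9ac) and 23.2% (H3K27me3), between plasma and none 56.1% (H3K9ac) and 32.8% (H3K27me3). With a fold of 8 or more, mean shares were, between the sides 92.3% (H3K4me3), 47.0% (H3K9ac) and 54.6% (H3K27me3), between the ages 88.8% (H3K4me3), 28.4% (H3K9ac) and 71.5% (H3K27me3), between the plasma donors 87.2% (H3K9ac) and 6.67% (H3K27me3), between plasma and none 75.0% (H3K9ac) and 35.0% (H3K27me3). With at least 50% of the smaller peak overlapping, mean shares were, between the sides 74.1% (H3K4me3), 50.3% (H3K9ac) and 51.7% (H3K27me3), between the ages 73.3% (H3K4me3), 52.7% (H3K9ac) and 67.5% (H3K27me3), between the plasma donors 58.7% (H3K9ac) and 22.9% (H3K27me3), between plasma and none 53.7% (H3K9ac) and 51.3% (H3K27me3). With peaks within 1 kb joined, mean shares were, between the sides 74.1% (H3K4me3), 56.5% (H3K9ac) and 55.0% (H3K27me3), between the ages 73.1% (H3K4me3), 59.0% (H3K9ac) and 69.8% (H3K27me3), between the plasma donors 23.3% (H3K27me3), between plasma and none 60.0% (H3K9ac) and 54.5% (H3K27me3). In bases, mean shares were, between the sides 90.5% (H3K4me3), 62.3% (H3K9ac) and 58.8% (H3K27me3), between the ages 88.6% (H3K4me3), 63.5% (H3K9ac) and 74.1% (H3K27me3), between the plasma donors 73.1% (H3K9ac) and 36.0% (H3K27me3), between plasma and none 64.3% (H3K9ac) and 61.5% (H3K27me3). The shorter list was set from all peaks and in several pairs is the longer one at a fold of 8 or more, so the low H3K9ac and H3K27me3 shares there follow in part from list length: for H3K9ac at 21 months 5736 ipsilateral peaks stood against 1215 contralateral ones, and on the contralateral side 10152 13-month peaks against 1215, and for H3K27me3 at 13 months 1696 contralateral peaks against 334.

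The odds ratio for the same direction kept its direction for the side in every mark and alternative that gave a value, from 1.62 to 62.8 for H3K4me3 and H3K27me3 and from 0.387 to 0.592 for H3K9ac. With a fold of 8 or more it was no longer past the threshold for H3K4me3, at 1.62 for the side and 2.62 for age, and it turned round for H3K9ac and age, at 3.83. H3K4me3 regions of at least 1 kb gave no odds ratio for age, since 1 direction was empty. The relation of H3K9ac to H3K27me3 in 21-month ipsilateral tissue passed the threshold of Fisher's exact test over regions with equal numbers, at 0.859. Bivalent peaks at 21 months fell from 8587 to 5038 ipsilateral and from 12865 to 6339 contralateral with equal numbers.

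The difference in the percentage of constitutive H3K4me3 regions with a peak (ipsilateral minus contralateral, 21 minus 13 months, young minus old plasma, plasma minus none) was, for H3K9ac, -3.02 for side at 13 months, 2.19 for side at 21 months, 3.71 for age, ipsilateral, -1.51 for age, contralateral, -9.60 for young against old plasma, -8.98 for young plasma against none, 0.613 for old plasma against none, and for H3K27me3, 0.312 for side at 13 months, -7.29 for side at 21 months, 5.94 for age, ipsilateral, 13.5 for age, contralateral, 3.83 for young against old plasma, -15.9 for young plasma against none, -19.8 for old plasma against none percentage points. For H3K9ac with equal numbers of peaks, it was -2.22 for side at 13 months, 4.14 for side at 21 months, 2.81 for age, ipsilateral, -3.55 for age, contralateral, -5.96 for young against old plasma, -5.72 for young plasma against none and 0.243 for old plasma against none. For H3K9ac with a fold of 8 or more, it was 1.55 (turned round) for side at 13 months, 23.6 for side at 21 months, -24.3 (turned round) for age, ipsilateral, -46.3 for age, contralateral, -49.9 for young against old plasma, -26.2 for young plasma against none and 23.8 for old plasma against none. For H3K9ac with regions widened by 1 kb, it was -2.58 for side at 13 months, 3.28 for age, ipsilateral, -8.76 for young against old plasma and -8.28 for young plasma against none. For H3K27me3 with equal numbers of peaks, it was -3.21 (turned round) for side at 13 months, -2.87 for side at 21 months, -0.492 (turned round) for age, ipsilateral, -0.841 (turned round) for age, contralateral, 5.35 for young against old plasma, -4.55 for young plasma against none and -9.89 for old plasma against none. For H3K27me3 with a fold of 8 or more, it was -4.00 (turned round) for side at 13 months, 0.640 for age, ipsilateral, 4.16 for age, contralateral, 0.153 for young against old plasma, -1.36 for young plasma against none and -1.51 for old plasma against none. For H3K27me3 with regions widened by 1 kb, it was 1.35 for side at 13 months, -8.51 for side at 21 months, 6.43 for age, ipsilateral, 16.3 for age, contralateral, 3.39 for young against old plasma, -17.5 for young plasma against none and -20.9 for old plasma against none.

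Ratios of peak numbers moved by no more than 1.5 times in covered bases, where that for H3K4me3 (21 over 13 months, ipsilateral) turned round from 0.902 to 1.06. With a fold of 8 or more they turned round for the same H3K4me3 comparison, to 1.204, for H3K9ac, to 1.05 (ipsilateral over contralateral, 13 months), 4.72 (the same at 21 months), 0.537 and 0.120 (21 over 13 months, ipsilateral and contralateral), and for H3K27me3, to 0.197 (ipsilateral over contralateral, 13 months) and 1.08 (young over old plasma). They moved to 0.232 for H3K27me3 and side at 21 months, to 1.68 for H3K27me3 and age on the contralateral side, and for H3K9ac to 0.0665 for young over old plasma and 0.119 for young plasma over none.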

Other observations

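Per Mb, less of the X chromosome than of the autosomes lay under called peaks of every mark. No correction was made for the number of X copies or for gene density, so less of a mark per copy was not shown. Bases under peaks per Mb of chromosome were 0.479 to 0.495 times the autosomal value for H3K4me3, 0.182 to 0.305 times for H3K9ac and 0.0862 to 0.147 times for H3K27me3 over the lists of each mark. The lowest H3K9ac value was that with plasma of 22-month rats and the highest that with plasma of 3-month rats.

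Some stretches returned under several patterns. Between 52595518 and 52998868 on chromosome 2 lay 5 of the named H3K27me3 regions, from the ipsilateral-only, the 21-month-only and the 13-month-only groups together. This stretch held 80 to 115 H3K27me3 peaks in the untreated lists and 66 in each plasma list. At the start of chromosome 20, between 65435 and 189337, lay 4 named regions of 4 patterns over all 3 marks: the strongest H3K4me3 regions of the 13-month and of the 21-month group, an H3K9ac region with plasma of 22-month rats alone and an H3K27me3 region with plasma of 3-month rats alone. These stretches were singled out after their values were seen.

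Strong H3K27me3 peaks with plasma of 22-month rats were mostly absent from untreated tissue: 68 of the 97 peaks of fold 8 or more had no peak there, against 7 of 105 with plasma of 3-month rats. All but 5 of the 97 had a peak in the list with plasma of 3-month rats, which lay in the same processing run. With equal numbers of H3K9ac peaks, the 13-month ipsilateral list shared 57.2% with the 21-month contralateral and 57.3% with the 21-month ipsilateral list, and the 13-month contralateral list 58.3% and 62.1%. Chromosome 10 held 7.68% of these peaks with plasma of 3-month rats, 7.79% in 21-month contralateral tissue, 9.14% with plasma of 22-month rats and 9.19% in 21-month ipsilateral tissue.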
